A study of Mus musculus with 6 samples.

How the data were processed

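Expression was measured in hair follicle bulbs of mice at postnatal day 9 on 6 one-colour oligonucleotide arrays, in 3 groups of 2 (emN1, anN1 and wild-type). The group and replicate of each array came from the sample titles. The series' design text states that the arrays were hybridised in 2 sets and that anN1 and wild-type both served as controls. The replicates are labelled biological, but the sources used here do not say whether they came from separate animals, so p-values measure the spread between these samples.

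The deposited values are an intensity per probe set on a linear scale. MAS5 is named in the submitters' processing notes; its version and other settings are not given in the sources used here. The authors' values had a mean of 1500 between the 2nd and 98th percentiles on every array, found from the values, and were not rescaled. No detection calls were used. The table held 45101 probe sets, 64 of them controls that were left out of all tests. Signal over background was judged from 20 bacterial control probe sets that were not detected: their 120 values had a median of 24.4 and a 95th percentile of 112.

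Probe sets were named from the platform annotation, in which 34958 had 1 gene symbol, 932 several and 9211 none. Symbols were looked up by gene identifier in an annotation of the assembly GRCm38.p6, used for names alone, where 34754 matched and 0 changed. No gene was named from a probe set with several symbols or none. A gene was represented by its kept probe set with the highest mean signal. Among 342 called genes with several kept probe sets, 0 had another past the threshold in the opposite direction and 40 had one of opposite sign. Several named genes had another kept probe set that did not pass, and not every case is printed.

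Signals were transformed to log2(signal + 17.8), the addend being the 10th percentile of all values, so that log2 differences understate changes of dim genes. Probe sets in the upper 60% of mean log2 signal were kept (27022 probe sets, 12611 genes). Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over the kept probe sets and a threshold of 0.05. One fit set 2 emN1 against 4 control arrays (3 residual degrees of freedom) and another had 3 groups (2 residual degrees of freedom); array set was a term of both. The prior degrees of freedom were 5.30 with the trend and 2.22 without it, and the median residual SD was 0.449 in the dimmest and 0.131 in the brightest of 4 equal groups of kept probe sets. Figures were drawn with matplotlib 3.10.9.

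Replicate numbers of emN1 and anN1 are the same as their array set in the design text, which pairs them. Differences between replicates 1 and 2 correlated with r = 0.38 across 27022 probe sets between emN1 and anN1, which are not independent replicates, and with -0.19 and -0.02 for pairs that include wild-type, whose numbers mark no set.

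Of 27 gene lists covering pathways and cell types, the 25 with at least 5 kept genes were tested with camera at a preset correlation of 0.01, adjusted over the lists. An estimated correlation and fry were alternatives. The correlation of the immune cell list was estimated at -0.026, under the preset 0.01, yet its unadjusted camera p rose from 4.14e-10 to 0.00622. A call lost with the estimated correlation therefore does not by itself show that the genes of a list are correlated. With an estimated correlation camera uses the residual degrees of freedom of the fit (3 or 2), not a number near that of the genes. An adjusted p under 0.05 is then hard to reach with 6 arrays, whatever the list. In camera with the preset correlation 13 lists passed, with the estimated one 0 (6 at an unadjusted p under 0.05), and with fry 14. Fry tests whether a list's genes move on balance in one direction and makes no comparison with other genes. It lost the keratin-associated, cortex and cuticle, and adipocyte lists (fry adjusted p = 0.0520, 0.0674 and 0.0679). It added the dermal papilla, BMP and TGF-beta, skeletal muscle, and sebaceous gland lists (fry adjusted p = 0.0422, 0.0267, 0.0293 and 0.0488). The groups, tests, thresholds, lists, naming rule and most alternatives were fixed before the data were examined. List tests between anN1 and wild-type and the comparison of directions between array sets were added later.

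Genes were named by rule: Notch1; the 15 genes with the largest change in each direction among those past the threshold with each emN1 array on the same side of every control of its set; from each list up to 4 genes past the threshold by size of change, or otherwise the 2 with the smallest unadjusted p as values; and up to 5 per direction in each other comparison. Genes named outside the rule are said to be so. Hes1, Dtx4, Bcl6, Krt75, Krt17 and Dcn are of this kind.

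The limma step was tested on simulated data for emN1 against controls, with 27022 probe sets, 200 of them changed, in 10 draws whose variances were drawn from the fitted trend, which favours the fit with the trend. With the trend, 24.6% of changes of 1 log2 unit and 67.6% of changes of 2 were recovered, and 5.24% of calls were false; without it, 0.100% and 42.5% were recovered and 1.62% were false. In 5 draws a list of 20 genes raised by 0.5 passed in 5 with the preset and in 5 with the estimated correlation, at an unadjusted p under 0.05, and an unmoved list passed in 1 with the preset and in 0 with the estimated correlation.

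Alternatives covered the pseudocount, the filter on dim probe sets, normalization, the set term, the variance model, the threshold, the list test and leaving out each array. An alternative that raised signals to background and one without the wild-type arrays were chosen after seeing the data.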

Results

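Gene expression was measured on 6 mouse oligonucleotide arrays hybridised with total RNA from hair follicle bulbs at postnatal day 9, when the first coat is growing. Hair bulbs called emN1 came from skin in which Notch1 had been deleted in the embryo and lack functional Notch1 (2 arrays). Bulbs called anN1 came from an area deleted only in the growth phase, called anagen, and still had functional Notch1 (2 arrays), and wild-type bulbs made up the third group (2 arrays). The labels call the 2 replicates of each group biological. Both anN1 and wild-type bulbs served as controls, so that the central comparison sets 2 emN1 arrays against 4 control arrays. The arrays were hybridised in 2 sets, the first holding 1 emN1 and 1 anN1 array and the second the other 4, and the small number of arrays limits the precision of every value.

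Notch1, the receptor whose loss defines the emN1 group, was lowest in emN1. The brighter of its probe sets gave 6498 and 6292 signal units in the emN1 arrays, 15077 and 12527 in the anN1 arrays, and 23750 and 34070 in the wild-type arrays. In emN1 it fell by 1.55 on the log2 scale (SE 0.35; 2 against 4 arrays), with a limma Benjamini-Hochberg adjusted p of 0.0491. The second probe set fell by 0.96 (SE 0.17). Against each kind of control alone, the brighter probe set differed by -1.10 (SE 0.18) from anN1 and by -2.23 (SE 0.20) from wild-type. Both passed limma with the intensity trend (Benjamini-Hochberg adjusted p = 0.0282 and 0.00344) and neither passed without it. The second probe set, at -0.88 and -1.07, passed in neither comparison (limma adjusted p = 0.0846 and 0.0620). The labels do not say which part of the gene was deleted, so a probe set that lies outside that part would check nothing about the labels. The call on the Notch1 emN1 minus controls log2 value was lost without emN1 replicate 2 (adjusted p = 0.423), emN1 replicate 1 (0.212), anN1 replicate 1 (0.207) or wild-type replicate 1 (0.0996), and also with a pseudocount of 1 (0.0528), without the filter on dim probe sets (0.0571) and without the set term (0.0935). Its direction was the same in all of these, as both emN1 signals lay under every control signal.

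Among known Notch target genes, 2 of the 13 measured fell in emN1, none rose and 11 did not pass the test. Adjusted over the list alone, 3 fell and 2 rose. Nrarp, a feedback inhibitor of Notch signalling, fell by 0.81 log2 units (SE 0.12) and Heyl, a transcriptional repressor induced by Notch, by 0.87 (SE 0.19), although the other 2 Heyl probe sets, at -0.32 and -0.43, did not pass. Hes1, another repressor induced by Notch, did not pass and is named after its values were seen. It differed by -0.38 (SE 0.16). In the second array set its signal was 4098 in emN1, 4045 in anN1, and 4878 and 5022 in wild-type. The 2 genes that rose over the list alone were Dtx4 (log2 0.84, SE 0.22) and Bcl6 (log2 0.77, SE 0.17), also named after their values were seen. The median of the list was -0.19, and camera with a preset correlation did not separate it from other genes (Benjamini-Hochberg adjusted p = 0.151; 0.471 with an estimated correlation). Against wild-type alone the median was -0.45 and the list passed with the preset correlation (adjusted p = 0.0273) but not otherwise (adjusted p = 0.382 with an estimated correlation). The list Notch target genes adjusted p was also under the threshold without anN1 replicate 2 (0.0497) and with the mean of all probe sets of a gene (0.0362). Of the 21 measured receptors, ligands and processing genes of the pathway, Notch1 fell and 20 did not pass; adjusted over the list alone 1 fell. The median of that list was -0.12 and its camera adjusted p was 0.748 after Benjamini-Hochberg adjustment (0.772 with an estimated correlation).

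Across the whole array, the numbers of probe sets and genes different between emN1 and controls by limma with Benjamini-Hochberg adjustment were 1020 of 27022 probe sets and 682 genes. Of the probe sets 650 were higher and 370 lower in emN1, and of the genes 451 and 231, and in all 682 each emN1 array lay on the same side of every control array of its own set. At an unadjusted p under 0.05 there were 4477 probe sets, where chance would give 1351. That count rests on a variance that follows signal intensity and on few arrays: limma without that trend called 0 (4044 at an unadjusted p under 0.05; smallest adjusted p 0.0521), and without emN1 replicate 2 it called 1, without emN1 replicate 1 it called 160, without anN1 replicate 1 it called 190, and without the set term 286. A comparison that needs no variance model, chosen after the data were seen, took the 3126 probe sets that differed at least 2-fold between emN1 and anN1 in the first set. Of these, 2085 (66.7%) differed in the same direction in the second set, 127 at least 2-fold the other way, against 58.6% in the same direction among all 27022. The share was 77.8% for those higher in emN1 and 57.6% for those lower, which is no more than among all probe sets. For the 587 in the brighter part of the table it was 89.3%, with 3 at least 2-fold the other way. The share among all probe sets joins both directions. Median array signal was lower in emN1 than anN1 in the first set (229 and 253) and higher in the second (263 and 241). The 57.6% therefore does not show that decreases fail to recur. Of the 1718 lower, 270 were at least 2-fold lower in the second set and 92 at least 2-fold higher.

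The 5 largest increases in emN1 among genes past the threshold were in genes of the hair shaft. Of 31 measured keratin-associated protein genes, which encode the matrix between the keratin filaments of the shaft, 15 rose, none fell and 16 did not pass (27 rose adjusted over the list alone). Krtap13-1 rose by 6.54 log2 units (SE 1.06), from a mean signal of 491 in the controls to 29888 in emN1, Krtap9-3 by 6.20 (SE 0.74) and Krtap17-1 by 5.50 (SE 0.77). Of 23 genes of the shaft cortex and cuticle, 6 rose, none fell and 17 did not pass (14 rose and 3 fell adjusted over the list alone). Among them were the cortex keratins Krt86, up by 6.26 (SE 0.77), Krt34, up by 5.87 (SE 0.87), and Krt81, up by 4.59 (SE 0.49). Control signals for these genes were low: 16 and 17 of the 31 keratin-associated genes in the wild-type arrays and 13 in anN1 replicate 2 lay under 112, the 95th percentile of undetected bacterial control probe sets, so that their fold changes are uncertain in size.

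The median log2 difference was 3.61 for the keratin-associated list and 1.22 for the cortex and cuticle list. Its size differed between the array sets, at 1.07 in the first and 5.11 in the second for the keratin-associated list and at 0.70 and 1.61 for the other. The control was anN1 alone in the first set and anN1 with wild-type in the second, so these values do not compare the sets alone. The median keratin-associated signal was 3260 in emN1 and 1127 in anN1 in the first set, and 5573 and 199 in the second. With anN1 as the only control the sets thus still differed in size, and the 2 anN1 replicates differed from each other. In camera with a preset correlation both lists passed (Benjamini-Hochberg adjusted p = 1.20e-19 and 1.06e-05), and with an estimated correlation neither did (adjusted p = 0.208 and 0.227 with an estimated correlation). Neither passed fry (fry adjusted p = 0.0520 and 0.0674). The cortex and cuticle list was also not past the threshold without emN1 replicate 2 (adjusted p = 0.0682). In the list for the inner root sheath, the layer that moulds the shaft, 4 of 17 measured genes rose and 13 did not pass (7 rose adjusted over the list alone), with a median of 0.21. Examples were Krt26, up by 2.97 (SE 0.32), and Krt72, up by 1.08 (SE 0.12), both keratins of that layer, and the peptidylarginine deiminase Padi3, up by 1.11 (SE 0.21). The list passed camera with a preset correlation (Benjamini-Hochberg adjusted p = 7.58e-04) and did not with an estimated one (adjusted p = 0.208 with an estimated correlation).

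**Figure D1:**
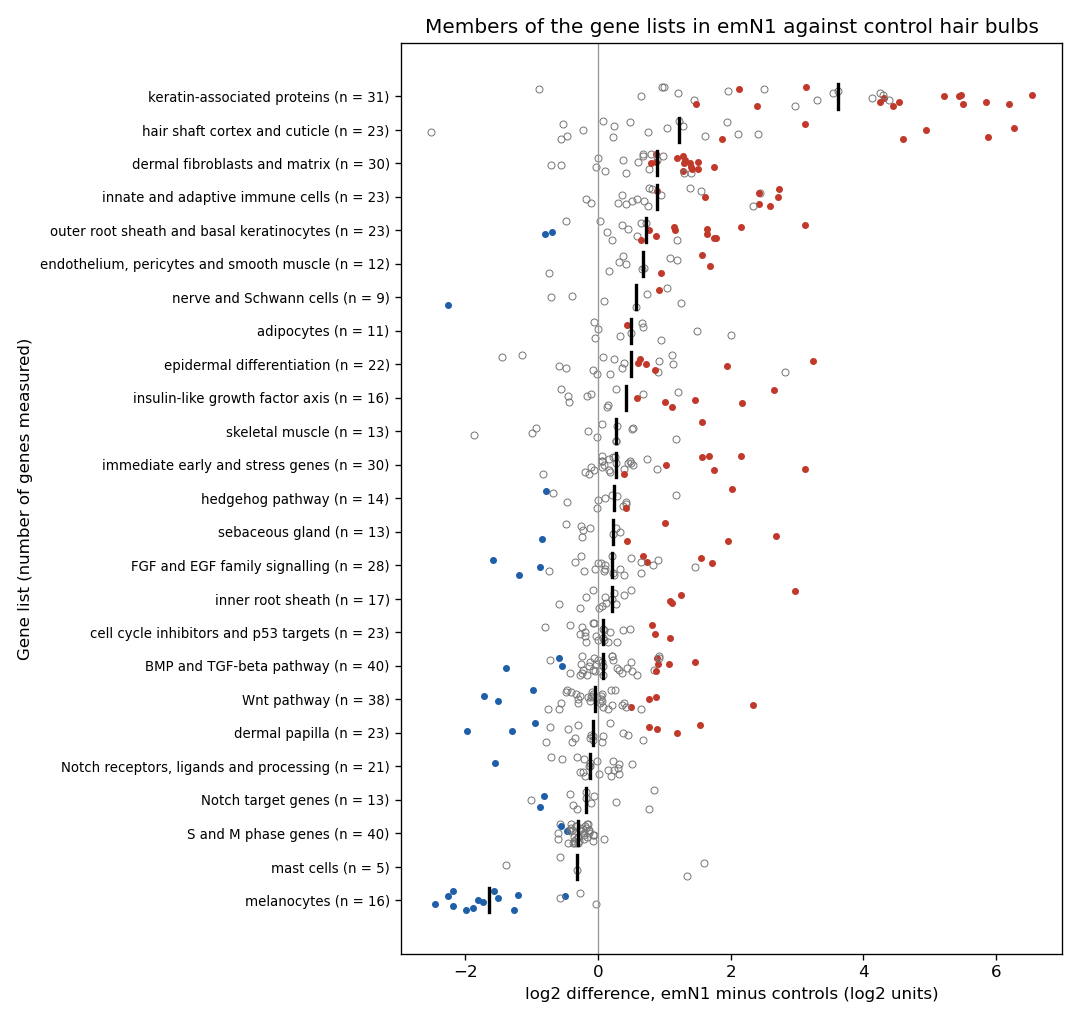
Each point is 1 measured gene of a list, placed by its log2 difference between emN1 (2 arrays) and controls (4 arrays), in log2 units; filled points passed a limma Benjamini-Hochberg adjusted p of 0.05 (red higher, blue lower), open points did not, and black bars are list medians. The keratin-associated protein list has a median of 3.61 and the melanocyte list one of -1.65.

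In the list for the outer root sheath and basal keratinocytes, 11 of 23 measured genes rose, 2 fell and 10 did not pass (16 rose and 2 fell adjusted over the list alone). Krt15, a keratin of basal and bulge keratinocytes, rose by 1.77 (SE 0.15). Krt6a rose by 2.16 (SE 0.34), with 1 of its 3 probe sets past the threshold. Krt16 rose by 3.13 (SE 0.48), with 1 control array, at 63.3, under background. Both are keratins induced in stressed and wounded epidermis. The matrix protein gene Postn rose by 1.75 (SE 0.29). The 2 that fell, Krt75 (log2 -0.80, SE 0.12) and Krt17 (log2 -0.69, SE 0.14), are keratins of the follicle and are named after their values were seen. The list median was 0.72, and the list passed camera with a preset correlation (Benjamini-Hochberg adjusted p = 9.12e-10) but not with an estimated one (adjusted p = 0.132 with an estimated correlation). Of 22 measured genes of epidermal differentiation, 6 rose and 16 did not pass (10 rose and 2 fell adjusted over the list alone). They included Calm4, a calcium-binding protein of differentiating keratinocytes, up by 3.25 (SE 0.31), Klk7, a protease of shedding epidermis, up by 1.95 (SE 0.26), and the cornified envelope gene Sprr1a, up by 0.72 (SE 0.10). That list had a median of 0.49 and a camera adjusted p of 2.56e-04 with a preset correlation after Benjamini-Hochberg adjustment (adjusted p = 0.208 with an estimated correlation).

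Of 16 measured melanocyte genes, 13 fell in emN1, none rose and 3 did not pass (14 fell adjusted over the list alone). Trpm1, a cation channel of melanocytes, fell by 2.46 (SE 0.10). Sox10, a transcription factor of the melanocyte and Schwann cell lineages, fell by 2.27 (SE 0.32), though its other probe set, at -0.68, did not pass. Mc1r, the melanocortin receptor, fell by 2.19 (SE 0.22) and the melanosome protein gene Gpr143 by 2.18 (SE 0.23). The list median was -1.65, with -1.65 in the first array set, against anN1, and -1.55 in the second, against anN1 and wild-type. It passed camera with a preset correlation (Benjamini-Hochberg adjusted p = 2.54e-20) and did not with an estimated correlation (adjusted p = 0.144 with an estimated correlation). Kitl, the ligand of the receptor Kit on which melanocytes depend, fell by 1.59 (SE 0.12), and Kit itself, given as a value because it did not pass, differed by -0.58 (SE 0.15).

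**Figure D2:**
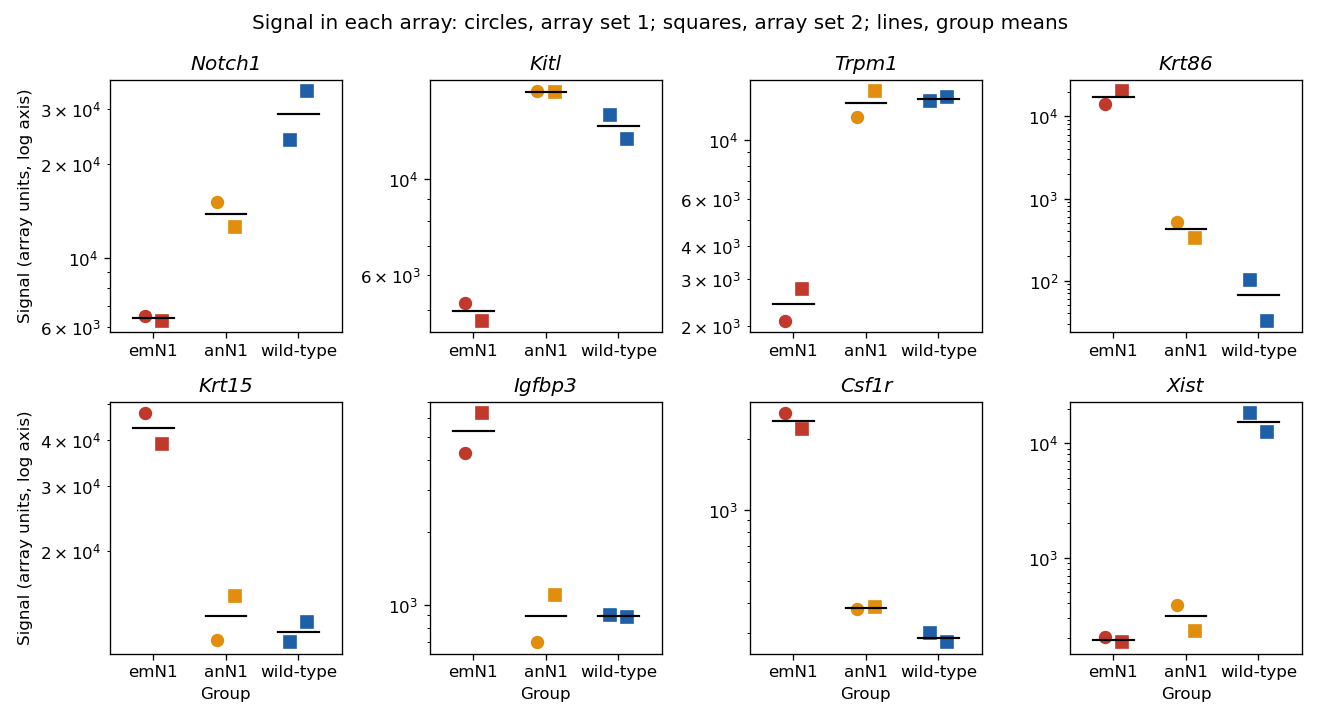
Signal in array units on a logarithmic axis for 8 genes in each of the 6 arrays, by group, with circles for the first array set, squares for the second and black lines for group means. The signal of Kitl was 5187 and 4721 in the emN1 arrays and at least 12383 in each of the 4 control arrays, while that of Xist was 18376 and 12671 in the wild-type arrays and at most 390 in the other 4.

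Of 40 measured genes of the S and M phases of the cell cycle, 2 fell, Ccnb2 (log2 -0.55, SE 0.11), a cyclin of mitosis, and Bub1b (log2 -0.46, SE 0.10), a spindle checkpoint kinase, and 38 did not pass. Adjusted over the list alone 14 fell. The list median was -0.30, with 39 of 40 values below 0, and camera with a preset correlation gave a Benjamini-Hochberg adjusted p of 2.65e-09 (adjusted p = 0.216 with an estimated correlation). Of 23 measured cell cycle inhibitors and p53 targets, 3 rose, none fell and 20 did not pass (3 rose and 2 fell adjusted over the list alone). The 3 were Cdkn1c, up by 1.08 (SE 0.18), and Cdkn2b, up by 0.81 (SE 0.15), both inhibitors of cyclin-dependent kinases, and Trp53inp1, a p53 target, up by 0.85 (SE 0.15). The list median of 0.07 did not pass camera (Benjamini-Hochberg adjusted p = 0.398; 0.471 with an estimated correlation).

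Of 30 measured fibroblast and matrix genes, 14 rose and 16 did not pass (22 rose adjusted over the list alone). Thy1, a surface protein of fibroblasts, rose by 1.51 (SE 0.16). Others were the fibrillar collagen gene Col5a2, 2.84-fold higher (SE 0.12 on the log2 scale), and Lox, which cross-links collagen, up by 1.41 (SE 0.24). The other Col5a2 probe set, at 0.58 log2 units, did not pass. The list median was 0.88. Of 23 measured immune cell genes, 7 rose and 16 did not pass (12 rose adjusted over the list alone). Csf1r, a receptor of macrophages, rose by 2.72 (SE 0.24), though the lowest of its 3 probe sets differed by 0.13 and 2 passed. The protease gene Ctss was up by 2.71 (SE 0.36), and the antigen-presentation gene H2-Aa up by 2.43 (SE 0.48) from control signals near background, while a second H2-Aa probe set differed in the opposite direction. The immune list had a median of 0.88. Outside it, the macrophage receptor gene Trem2 fell by 2.07 (SE 0.44), with 1 emN1 signal, 32.0, under background. Of 12 measured genes of endothelium, pericytes and smooth muscle, 3 rose and 9 did not pass (4 rose adjusted over the list alone). The 3 were Tagln, up by 1.69 (SE 0.17), and Acta2, up by 0.95 (SE 0.13), of contractile cells, and the pericyte marker Cspg4, up by 1.57 (SE 0.16), with a list median of 0.67. Camera with a preset correlation passed these 3 lists (Benjamini-Hochberg adjusted p = 8.42e-16, 2.07e-09 and 2.59e-04); each had an adjusted p = 0.132 with an estimated correlation.

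In the insulin-like growth factor list, 6 of 16 measured genes rose, none fell and 10 did not pass (6 rose adjusted over the list alone). The binding protein genes Igfbp3, Igfbp2 and Igfbp7 rose by 2.65 (SE 0.17), 2.17 (SE 0.22) and 1.46 (SE 0.13), and Htra1, a protease that cleaves binding proteins, rose by 1.11 (SE 0.13). The median of 0.42 passed camera with a preset correlation (Benjamini-Hochberg adjusted p = 3.28e-04) and not otherwise (adjusted p = 0.208 with an estimated correlation). In the fibroblast and epidermal growth factor list, 4 of 28 measured genes rose, 3 fell and 21 did not pass (7 rose and 3 fell adjusted over the list alone). The receptor ligand genes Tgfa and Ereg rose by 1.72 (SE 0.22) and 1.55 (SE 0.19), with 1 Tgfa probe set differing in the opposite direction, and Fgf5, which ends the growth phase, fell by 1.19 (SE 0.21). This list did not pass camera (median 0.22; Benjamini-Hochberg adjusted p = 0.0657; 0.208 with an estimated correlation), though the list FGF and EGF family signalling adjusted p was 0.0386 without wild-type replicate 1.

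Outside these lists, Gm94 fell by 3.61 (SE 0.27), Apobec1, a cytidine deaminase that edits RNA, fell by 3.36 (SE 0.34), and Ildr2 fell by 3.18 (SE 0.44). The emN1 signals of Apobec1 (76.5 and 34.0) and Ildr2 (69.6 and 15.2) lay under the background limit of 112, so that the sizes of these decreases are uncertain. With signals raised to that limit, an alternative chosen after seeing the data, the Apobec1 emN1 minus controls log2 value was -2.38 and the Ildr2 emN1 minus controls log2 value was -1.77, both past the threshold. Gsta2, a glutathione transferase, fell by 2.31 (SE 0.21), Syt7, a calcium sensor of vesicle fusion, fell by 2.27 (SE 0.24), and Tgm2, a transglutaminase, fell by 2.21 (SE 0.35). Of the 92 genes named by rule that passed between emN1 and controls, 91 lost their call without emN1 replicate 2, 62 without emN1 replicate 1, 59 without anN1 replicate 1, 16 without wild-type replicate 1, 14 without anN1 replicate 2 and 4 without wild-type replicate 2. Without the variance trend limma called none of the 92, and without the set term 45 lost their call, while 0 changed direction in any alternative. Few reversals could arise, because in all called genes each emN1 array lay on the same side of every control of its set. The single-array removals are also not independent of each other. Without emN1 replicate 1 or anN1 replicate 1 the set term absorbs the array left in the first set, so both fits rest on the second. Without emN1 replicate 2 the difference rests on emN1 replicate 1 against anN1 replicate 1.

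The changes in emN1 were also looked for against each kind of control alone. Krtap9-3, Krt86 and Krtap13-1 rose by 6.08, 5.29 and 5.12 log2 units against anN1, whose bulbs have functional Notch1, and Gm94 fell by 3.39. The signal of Krtap9-3 in anN1 replicate 2 was under the background limit of 112, so that the size of its increase is uncertain. Limma with Benjamini-Hochberg adjustment counted 545 probe sets different between emN1 and anN1, 366 higher and 179 lower in emN1, with 3633 at an unadjusted p under 0.05. Against wild-type, Krtap13-1, Krt86 and Krt34 rose by 8.68, 7.72 and 7.56, and Gm94 fell by 3.95, while Eif2s3y, up by 8.96, and Xist, which fell by 6.40, are sex-linked. The wild-type signals of Krtap13-1 (119 and 37.2), Krt86 (103 and 32.7), Krt34 (48.2 and 165) and Eif2s3y (32.2 and 5.35) lay mostly under that limit, which leaves the sizes of these increases uncertain. There were 584 probe sets different between emN1 and wild-type, 414 higher and 170 lower, with 3559 at an unadjusted p under 0.05. The melanocyte median was -1.79 against anN1 and -1.44 against wild-type, and the fibroblast and matrix medians were 0.91 and 0.84. Without the variance trend limma called 0 in both comparisons (3109 and 3003 at an unadjusted p under 0.05), and without the set term it called 42 and 215. The count against anN1 was 0 without either emN1 or either anN1 replicate, 1269 without wild-type replicate 1 and 1210 without wild-type replicate 2. The count against wild-type was 30 and 0 without emN1 replicates 1 and 2, 46 and 56 without anN1 replicates 1 and 2, and 1375 without wild-type replicate 1.

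The 2 kinds of control were compared with each other to see what else they differ in. Limma with Benjamini-Hochberg adjustment counted 20 probe sets different between anN1 and wild-type, 14 higher and 6 lower in anN1, with 984 at an unadjusted p under 0.05, where chance would give 1351. Eif2s3y, Uty and Kdm5d, carried on the Y chromosome, were higher in anN1 by 8.75, 5.44 and 4.68 log2 units, sizes that are uncertain because all their wild-type signals were under the background limit of 112, and Xist, transcribed from the inactive X chromosome of females, fell by 5.81 (SE 0.31). All 4 emN1 and anN1 arrays had Eif2s3y signals of at least 10723 and Xist signals of at most 390, and the wild-type arrays had Eif2s3y signals of 32.2 and 5.35, so that the sex pattern of the arrays separates wild-type from the other groups. Of the shaft genes, Krt33a and Krtap17-1 were higher in anN1 by 2.66 (SE 0.15) and 2.69 (SE 0.25; wild-type signals of 107 and 108, under background), and Selenbp1, a selenium-binding protein of the same list, fell by 4.58 (SE 0.26). Tmem87a fell by 5.05 (SE 0.43), with 1 anN1 signal, 89.2, under background. Without the variance trend limma called 0 (1118 at an unadjusted p under 0.05), and it called 0 without any 1 of the emN1 or anN1 replicates, 173 without wild-type replicate 1 and 80 without wild-type replicate 2.

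Array set 2 differed from array set 1 in 3939 probe sets by limma with Benjamini-Hochberg adjustment, 2232 higher and 1707 lower. The count comes from the fit that joins anN1 and wild-type as controls. Both wild-type arrays are in set 2, so it can also hold differences between anN1 and wild-type, sex among them. The ratio of 5' to 3' signal of beta-actin, a sign of RNA integrity and labelling, was 0.218 and 0.177 in the first set and between 0.370 and 0.419 in the second. Within sets it was 0.218 in emN1 and 0.177 in anN1, and 0.419 and 0.418. The same ratio for Gapdh was 0.209 in emN1 and 0.144 in anN1 in the first set, 0.204 and 0.215 in the second, and 0.184 and 0.199 in the wild-type arrays, so it did not separate the sets and differed between emN1 and anN1 in the first.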

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

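All tests weighed here were chosen after the result was seen, except the comparison of independent array sets for the anN1 shaft genes, which was written beforehand. Of 4 control probe sets for the Cre recombinase of bacteriophage P1, which no comparison used, 2 gave signal over the background limit of 112 in all emN1 and anN1 arrays and under it in wild-type. The mean of 1 such probe set was 438 (SD 53.9, 4 arrays) against 70.7 (SD 11.7, 2 arrays), and that of another was 435 (SD 123) against 16.7 (SD 17.6). An exact two-sided permutation test within the second array set, which holds both wild-type arrays, gave p = 0.333 for both, the smallest that its 3 splits allow. Another had a mean of 152 (SD 52.2) against 22.2, with emN1 replicate 2 under background at 93.7, and the last, at 52.7 (SD 40.8) against 3.69, was under background in all arrays (exact permutation p = 0.333 for each in the same test). The labels do not name a recombinase.

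Of 16 melanocyte genes 13 fell in emN1 (median -1.65; adjusted p = 0.144 for the list with an estimated correlation). A smaller share of hair bulb in the emN1 samples, as the only cause, would lower the dividing matrix cells by about as much. The S and M phase genes had a median of -0.303 (quartiles -0.401 and -0.175), above the upper melanocyte quartile of -1.05. This argues against it as the only cause, if those genes mark matrix cells alone. Of the 40 genes 39 were below 0, so a smaller share as part of the cause is not excluded. Sex of the mice is also argued against, because the median was -1.79 between emN1 and anN1, whose 4 arrays all show the male pattern of sex-linked genes. Fewer melanocytes, lower expression in each, a smaller bulb share as part of the cause and a difference in hair cycle timing remain open. No biological explanation was tested.

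In emN1 15 of 31 keratin-associated and 6 of 23 cortex and cuticle genes rose against the controls. Between anN1 and wild-type 2 of 31 keratin-associated and 5 of 23 cortex and cuticle genes passed as higher. In camera the list calls were lost in both comparisons (adjusted p = 0.208 and 0.227, and 0.460 for both lists, with an estimated correlation). That loss by itself decides little, as this test had only 3 and 2 degrees of freedom. For emN1 against anN1, sex is argued against by a median of 3.05 over 31 keratin-associated genes (lower quartile 1.46). For anN1 against wild-type the median was 1.34, but no anN1 array shares the sex pattern of a wild-type array, so sex, breeding and deletion cannot be told apart. Genes picked on the first set alone, 200 per direction of emN1 minus anN1, had medians of 0.196 (higher in emN1) and 0.035 (lower in emN1) between anN1 and wild-type in the second set, a difference of 0.161, above all 10000 random picks of genes (permutation p = 0.0001, the smallest they can give; genes are not independent). Shaft genes, whose higher values in anN1 are the pattern in question, were not left out of the picks. The random picks were not matched for signal or spread. The difference therefore cannot decide whether anN1 bulbs share part of the emN1 increases. Genes lower in emN1 went both ways between anN1 and wild-type (melanocyte median 0.28, Notch target median -0.18, Notch1 -1.13 but not past the threshold). Sex separates the same arrays, and hair cycle timing was not tested.

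In emN1, 14 of 30 fibroblast, 11 of 23 basal keratinocyte and 7 of 23 immune genes rose, and each list call was lost with an estimated correlation (adjusted p = 0.132). A lower share of matrix cells, as the only cause, would raise the other cell types alike. But the fibroblast median lay 0.967 above that of the dermal papilla list (permutation p = 3.70e-04, 30 and 23 genes, which are not independent) and melanocyte genes fell. The dermal papilla list was itself mixed, with 4 genes that rose and 3 that fell. A lower share as part of the cause is not excluded, as 39 of 40 S and M phase genes were below 0 (median -0.303). More connective tissue around the follicle stays open: the 8 brightest fibroblast and matrix genes had a median of 1.08 and 6 of them rose, but Dcn, the brightest and named after its values were seen, differed by -0.0025. Of the 30 fibroblast genes 2 and of the 23 dermal papilla genes 11 are held by another list, and without these the difference was 0.96 (28 and 12 genes; permutation p = 6.90e-04). Whether cells in the bulb changed or tissue was carried along in the dissection was not tested.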

How the results depend on the processing

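The alternatives that raised signals to background or left out the wild-type arrays were chosen after seeing the data. Counts are of probe sets, in the order probe sets and genes different between emN1 and controls (1020 probe sets), probe sets different between emN1 and anN1 (545), probe sets different between emN1 and wild-type (584) and probe sets different between anN1 and wild-type (20). Without the intensity trend limma called 0 in all 4 (4044, 3109, 3003 and 1118 at an unadjusted p under 0.05), with smallest adjusted p of 0.0521, 0.158, 0.0917 and 0.273; all 1020, 545, 584 and 20 had an unadjusted p under 0.05 there. The cause was not tested. With no replicate block (no set term) the first 3 counts were 286, 42 and 215, and in a fit with the replicate number as paired block 288, 73 and 262. A random block for set gave 329 against anN1. An adjusted p of 0.10 gave 1732, 934 and 982, a 2-fold minimum gave 601 in the first, median centring gave 42 in the last, and the second array set alone gave 185 in the first; the causes of these differences were not tested beyond the fewer arrays.

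Leaving out single arrays gave 1 to 1092 probe sets for probe sets and genes different between emN1 and controls, 0 to 1269 probe sets different between emN1 and anN1, 0 to 1375 probe sets different between emN1 and wild-type and 0 to 173 probe sets different between anN1 and wild-type. A lone array was assumed to vary like the other groups, and every fit without 1 array had 1 residual degree of freedom in the 3-group design. Fits without either array of the first set took their emN1 estimate from the second set alone. Without the wild-type arrays emN1 against anN1 gave 1261, of which 912 were among the 1020. There 1 list that had not passed in the main test gained a call in camera with the preset correlation.

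Pseudocount, filter and quantile alternatives stayed within 1.5 times. Of the 92 named genes past the threshold 0 reversed. This says little, because each emN1 array already lay on the same side of every control of its set. The call was lost by 92 without the intensity trend, 45 without the set term and 13 without a filter. In the quantile, centring, pseudocount 1 and random block alternatives 1 to 11 lost it. Of the 13 lists past the threshold, 0 passed camera with an estimated correlation (6 of all 25 at an unadjusted p under 0.05) and 10 passed fry; 11 passed in all 15 other alternatives, while the cortex and cuticle and adipocyte lists (adjusted p = 0.0682 and 0.124) did not without emN1 replicate 2.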

Other observations

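Among 38 measured Wnt pathway genes, 4 rose, 3 fell and 31 did not pass (4 rose and 6 fell adjusted over the list alone). Dkk2, an inhibitor of Wnt signalling, rose by 2.33 (SE 0.38), Sfrp4, a secreted Wnt antagonist, fell by 1.73 (SE 0.24), its relative Sfrp1 was 2.83-fold lower, and Ccnd1, a G1 cyclin, fell by 0.99 (SE 0.13). Of 14 hedgehog pathway genes, 2 rose, 1 fell and 11 did not pass (4 rose and 3 fell adjusted over the list alone): Gas1, a co-receptor, rose by 2.01 (SE 0.27), Shh, the ligand made in the matrix, rose by 0.41 (SE 0.09), and Gli3, a transcription factor of the pathway, fell by 0.79 (SE 0.11). Of 40 genes of bone morphogenetic protein and TGF-beta signalling, 5 rose, 3 fell and 32 did not pass (7 rose and 3 fell adjusted over the list alone), with Tgfb2 up by 1.46 (SE 0.28) while the antagonist Sostdc1 fell by 1.39 (SE 0.22). In the dermal papilla list, 4 of 23 rose, 3 fell and 16 did not pass (5 rose and 4 fell adjusted over the list alone): Crabp1, a retinoic acid binding protein, fell by 1.97 (SE 0.20), Rspo3, an enhancer of Wnt signalling, was 2.46-fold lower, and Sox18 and Tbx18, transcription factors, rose by 1.54 (SE 0.33) and 1.18 (SE 0.20). None of these 4 lists passed camera with the preset correlation (Benjamini-Hochberg adjusted p = 0.398, 0.131, 0.131 and 0.818), or with an estimated one (adjusted p = 0.612, 0.359, 0.227 and 0.816 with an estimated correlation), except that the list hedgehog pathway adjusted p was 0.0421 without emN1 replicate 2.

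Of 30 measured immediate early and stress genes, 7 rose and 23 did not pass (10 rose and 1 fell adjusted over the list alone), among them Nr4a1, a nuclear receptor of early responses, up by 1.75 (SE 0.25), and Ccn2, a matrix-associated growth factor, up by 1.67 (SE 0.36). The list passed camera with the preset correlation (median 0.26; adjusted p = 3.01e-06; 0.132 with an estimated correlation). Of 11 adipocyte genes 1 rose, Scd1 by 0.44 (SE 0.09), and 10 did not pass (5 rose adjusted over the list alone; median 0.50; adjusted p = 0.00237; 0.208 with an estimated correlation). The other Scd1 probe set, at 0.08, did not pass. Of 13 sebaceous gland genes, 4 rose and 1 fell (4 and 1 adjusted over the list alone), with Elovl3, an enzyme of fatty acid elongation, up by 2.68 (SE 0.46) and Mgst1 down, at -0.84 (SE 0.11). That list did not pass camera (adjusted p = 0.398; 0.471 with an estimated correlation). Of 9 nerve and Schwann cell genes, Pmp22, a myelin protein gene, rose by 0.92 (SE 0.14) and Sox10 fell (1 and 1 adjusted over the list alone), and of 13 skeletal muscle genes Car3 rose by 1.57 (SE 0.23; 2 rose adjusted over the list alone). The other Car3 probe set, at 0.43, did not pass. The nerve and muscle lists had adjusted p values of 0.398 and 0.372 in camera (0.471 for both with an estimated correlation). None of 5 mast cell genes passed (1 rose and 2 fell adjusted over the list alone): Cpa3 differed by 1.60 (SE 0.43), and the list median of -0.31 and the downward direction of the test differ in sign from its mean of 0.13 (adjusted p = 0.660; 0.692 with an estimated correlation). Of 3 blood genes and 4 sex-linked genes, too few for a list test, none passed between emN1 and controls (0 rose and 1 blood gene fell adjusted over the list alone), where Car2 differed by -1.18 (SE 0.31) and Alas2 by 0.36 (SE 0.52).

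Between anN1 and wild-type, camera with the preset correlation passed 7 of 25 lists and with an estimated correlation 0 (2 at an unadjusted p under 0.05); these list tests were chosen after the data were seen. Keratin-associated genes had a median of 1.34 (adjusted p = 5.43e-21; 0.460 with an estimated correlation), cortex and cuticle genes 0.47 (adjusted p = 8.68e-14; 0.460 with an estimated correlation), and Notch target genes -0.18 (adjusted p = 0.00406; 0.460 with an estimated correlation). Limma called 0 members of the Notch target list and of the other 4 lists past the preset test. At an unadjusted limma p under 0.05 there were 3 Notch target, 4 inner root sheath, 8 epidermal, 7 melanocyte and 2 fibroblast genes. The medians were 0.11 for inner root sheath, 0.22 for epidermal and 0.28 for melanocyte genes (each adjusted p = 0.460 with an estimated correlation) and -0.12 for fibroblast and matrix genes (adjusted p = 0.617 with an estimated correlation).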
